A study of Mus musculus with 8 samples.

How the data were processed

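Binding of the transcription factor YY1 and of the histone acetyltransferase P300 was measured by CUT&RUN, in which an antibody directs a nuclease to cut out the DNA around its target protein. The cells were E14TG2a mouse embryonic stem cells, an established line, grown with LIF and 2 kinase inhibitors per the labels' protocols. The labels give 2 genotypes, wild type (WT) and a deletion in Alkbh5 named del-cIDR (ΔcIDR below), and 2 libraries for each antibody and genotype, 8 in all. IDR stands for intrinsically disordered region in the series title, and the labels do not expand the c. Alkbh5 encodes an RNA demethylase.

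The deposited data are 1 peak list per library in MACS2 narrowPeak format, so replicates were not pooled before peak calling. The submitters' processing notes name fastp, BWA, SAMtools, Picard, MACS2 and featureCounts and the genome build GRCm39, with no roles or versions. Whether a control library entered the peak calls is not given in the sources used here, and no control library was analysed here. Each deposited peak has a whole-number score, which equals 10 times its −log10 q without decimals in 99.79% to 99.99% of the peaks of a library. The fold enrichment deposited by the authors is a ratio of the reads at the peak summit to a local background. Whether that background came from the same library is not given, since a control library may have entered the calls. The deposited −log10 p and −log10 q values are those of the authors' peak caller, and the lowest −log10 q per library lay between 1.30 and 1.31, matching a q threshold of 0.05. The position of the summit in each peak, counted from the peak start, is also deposited. Score, fold and −log10 q belong to the authors' calls and were used in the report only to describe, rank or filter peaks within a list. The closing section also compares libraries through reads solved from the deposited fold and −log10 p, as described below. Coordinates are on GRCm39 and counted from 1.

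Peaks on chromosomes 1 to 19, X and Y were analysed. Mitochondrial peaks, peaks on unplaced scaffolds and peaks on a sequence named dm, which the labels do not describe, were left out, and made up 0.563% to 8.75% of a list. Read totals are not given in the files, so the number of peaks describes each library, and a region missing from a list was not called at the authors' threshold, which is not the same as unbound. In peak lists, intervals of shares (Wilson, 95%) cover counting error only. No 2 lists were copies of each other, with at most 23 intervals in common with equal start and end between any pair.

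Peaks of the 4 libraries of an antibody were merged where they shared at least 1 bp, and a library held a merged region when at least 1 of its peaks lay in it. Classes were ΔcIDR-only (both ΔcIDR libraries, no WT library), WT-only (the reverse) and present in all 4. Peak numbers were compared on the log2 scale as the mean of the ΔcIDR libraries minus the mean of the WT libraries, with a two-sided exact permutation test over the 6 assignments of 4 libraries, whose smallest p is 0.33. The difference between the antibodies in this log2 ratio was tested over 36 assignments, whose smallest p is 0.056, so neither test can pass 0.05. The labels do not say that the replicates came from separate cultures, so these p-values measure only the spread between these libraries, which may be technical. Counts of regions were set beside the same counts for the other ways to divide 4 libraries into pairs. Similarity of libraries was described by the share of peaks overlapped by at least 1 bp and by the Jaccard index, the bases covered in both lists over those covered in either. It was also computed on lists of equal length, holding the 3527 (YY1) or 1304 (P300) peaks with the highest −log10 q of each library.

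The regions named were set by a rule fixed before the data were examined: in each class, the 10 regions with the best mean percentile of −log10 q within the lists that hold them, of which the text gives the leading ones and summarises the rest. That rule also asked for the nearest gene, and for the genes Alkbh5, Yy1 and Ep300 and preset gene lists. No genome or annotation on GRCm39 was used here, and the gene table at hand is on another build, so regions are given by position, and shares of peaks at promoters, gene lists, YY1 motifs and shared promoters were not computed. In place of shared promoters, YY1 and P300 regions were overlapped by position, a test chosen after the data were examined. P300 regions were moved along their chromosome by 1000 random circular shifts, so 0.001 is the smallest p the shifts can give. Windows of 1 Mb with at least 10 peaks in every P300 library, and the shares of peaks by chromosome, were also chosen after the data were examined.

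For the closing section, whole reads at each summit and the background were solved from the deposited fold and −log10 p, taking fold as the reads plus 1 over the background plus 1 and p as a Poisson tail. With −log10 p under 250, 100% of the peaks tried in every library gave a whole number of reads within a relative tolerance of 2e-05. On simulated data, 100% of 2000 peaks were recovered and 0.594% of 1515 scaled, non-whole pileups were taken for whole reads. Offsets of single chromosomes were tested with 10000 permutations of regions over chromosomes and Benjamini-Hochberg adjustment over 20 chromosomes. In 50 simulated runs an offset of −0.3 on 1 chromosome was found in 100% of them, and 1.47% of 950 unchanged chromosomes were called. These runs used fewer permutations, an unadjusted threshold and regions simulated as independent. They therefore do not give the error rate of the adjusted test, or of regions that depend on each other. The assignment of 1300 simulated regions to classes was 100% correct. These regions lay far apart and their peaks always overlapped, so the check does not cover crowded or joined peaks.

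Alternatives were a −log10 q of at least 5, a fold of at least 5, lists of equal length, summits extended by 150 bp to each side in place of whole peaks, each library left out in turn, all sequences counted, and the replicate number as a block. A stricter rule, under which a peak must cover at least 50% of its region, and the removal of the 1 Mb windows were added after the data were examined. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.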

Results

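The series asks how a disordered region of the RNA demethylase ALKBH5 bears on where proteins sit on the genome, here by mapping YY1 and P300 in WT and ΔcIDR embryonic stem cells. YY1 is a zinc-finger transcription factor found at many promoters, and P300 is a histone acetyltransferase and coactivator often mapped to find enhancers. Each antibody and genotype had 2 libraries. The YY1 lists held 3527 to 15531 peaks on chromosomes 1 to 19, X and Y, with median widths of 227 to 287 bp. The P300 lists were shorter, with 1304 to 2487 peaks and median widths of 161 to 164 bp. The number of reads behind each list is not given in the files.

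YY1 peak lists were longer in ΔcIDR than in WT cells. The ΔcIDR libraries held 9178 and 15531 peaks, a mean of 12354.5 ± 4492 (SD, n = 2), and the WT libraries 3527 and 5842, a mean of 4684.5 ± 1637 (SD, n = 2). The ratio of geometric means was 2.63-fold, a log2 difference of 1.40, and both ΔcIDR lists were longer than both WT lists. Two-sided exact permutation of the genotype labels gave p = 0.33 (n = 2 per genotype), the smallest p this test allows with 4 libraries, so it cannot pass 0.05. The shorter ΔcIDR list exceeded the longer WT list by 3336 peaks, while the lists of the ΔcIDR replicates differed by 6353.

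**Figure D1:**
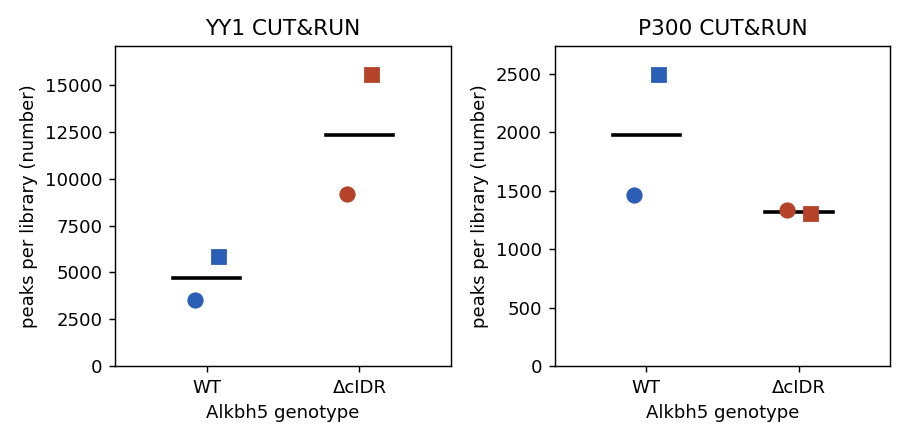
Peaks per library (vertical axis, number on chromosomes 1 to 19, X and Y) by Alkbh5 genotype, for YY1 on the left and P300 on the right, on different vertical scales. Circles are replicate 1, squares replicate 2 and black lines the means of 2 libraries; the YY1 means are 4684.5 in WT and 12354.5 in ΔcIDR, and the P300 means 1976.5 and 1321.

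Most YY1 regions of the WT cells were also called in ΔcIDR cells. Peaks of the 4 YY1 libraries merged into 20577 regions. Of the 2272 regions present in both WT libraries, 97.4% (Wilson 95% interval 96.6 to 97.9) lay in at least 1 ΔcIDR list and 88.6% in both. Of the 5686 regions present in both ΔcIDR libraries, 66.3% (65.1 to 67.6) lay in at least 1 WT list and 35.4% in both. The shorter WT lists limit the last share to at most 40.0%, so the shares in the opposite directions are not comparable. The 4 libraries shared 2012 regions. A further 1914 regions were ΔcIDR-only and 60 were WT-only. The other ways to divide the libraries into pairs gave 70 and 676 regions with equal replicate numbers together, and 248 and 210 with the numbers crossed. A single library held 13427 regions (65.3%), of which 8635 were in ΔcIDR replicate 2 alone and 3031 in ΔcIDR replicate 1 alone.

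The ΔcIDR-only count was lower when all lists had the same length, which removes the difference in peak number by construction. With the 3527 highest-ranked peaks of each library, 310 regions were ΔcIDR-only and 196 WT-only, against 1914 and 60 with the whole lists. With the class defined by a single library on one side, ΔcIDR-only regions numbered 10644 without ΔcIDR replicate 1, 5031 without ΔcIDR replicate 2 and 3295 without WT replicate 2. WT-only regions then numbered 1256 without WT replicate 1, 642 without WT replicate 2, 205 without ΔcIDR replicate 2 and 114 without ΔcIDR replicate 1.

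**Figure D2:**
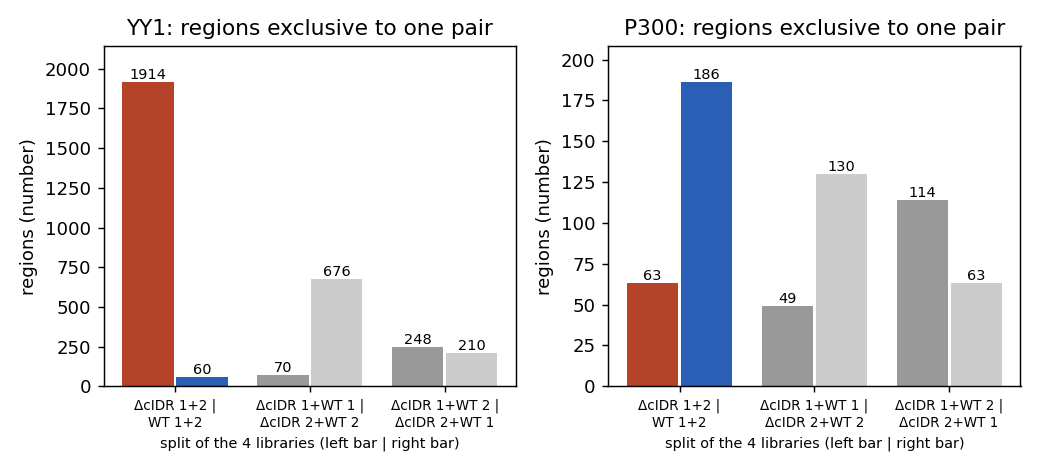
Number of merged regions (vertical axis) held by both libraries of a pair and by neither library of the opposite pair, for the 3 ways to divide the 4 libraries of an antibody. Red bars are ΔcIDR-only and blue bars WT-only regions, grey bars are pairs that mix genotypes; for YY1 the genotype division gives 1914 and 60, and for P300 63 and 186.

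The ΔcIDR-only regions ranked below the regions shared by all YY1 libraries. Their median percentile of −log10 q was 46.7 in ΔcIDR replicate 1 and 56.2 in replicate 2, against 85.7 and 91.2 for the shared regions of the same lists. Their median deposited fold was 5.01 and 5.25, against 7.19 and 8.18. WT-only regions also ranked below the shared regions, with median percentiles of 40.7 and 42.3 in WT replicates 1 and 2, against 68.4 and 77.7. The lower rank is therefore not particular to the ΔcIDR-only class. The best-ranked ΔcIDR-only region lay on chromosome 11 from 88864750 to 88865367, with folds of 9.26 and 9.95 in replicates 1 and 2. The next were on chromosome 9 from 96373802 to 96374056, with folds of 7.95 and 11.2, and on chromosome 11 from 107438753 to 107439094, with 9.17 and 9.63. A region on chromosome 11 from 79971536 to 79972418 followed, with 8.11 and 9.20. The 10 best-ranked regions of the class lay on 8 chromosomes, and their folds ranged from 7.72 to 11.2.

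A few of the 60 WT-only YY1 regions were strong. The region on chromosome 3 from 3005080 to 3005327 had folds of 11.0 and 10.5 in WT replicates 1 and 2, and a mean percentile of 99.0 within the WT lists. On chromosome 6 from 17840406 to 17840917 the folds were 14.9 and 16.6, with a mean percentile of 98.9. The regions on chromosome 16 from 17040092 to 17040308 and on chromosome 11 from 31872609 to 31872852 had mean percentiles of 96.9 and 94.8. From the fifth on, the mean percentile was at most 73.8. The chromosome 11 region was also WT-only in the P300 libraries, from 31872599 to 31872822, with P300 folds of 8.53 and 11.5.

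The strongest YY1 regions were the same in both genotypes. A region on chromosome 2 from 98496594 to 98497677 ranked at the top of all 4 YY1 lists, with folds of 23.5 and 29.3 in ΔcIDR and 20.3 and 20.8 in WT cells. It was followed by chromosome 6 from 103626050 to 103626254, chromosome 9 from 35216512 to 35216884, chromosome 1 from 24651739 to 24652301, and chromosome 12 from 3159872 to 3160119. The other 5 of the 10 best-ranked shared regions lay between 3000022 and 3024625 on chromosome 9. Most of these positions were not specific to YY1. Across both antibodies 80 regions were called in all 8 libraries, and they held 16 to 19 of the 20 best-ranked peaks of every library.

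At equal list length, YY1 libraries of one genotype were not always closer to each other than to libraries of the other genotype. The Jaccard index was 0.404 between the ΔcIDR libraries and 0.328 between the WT libraries, and 0.297 to 0.372 between genotypes. With whole lists, 63.9% (62.3 to 65.5) of the peaks of WT replicate 1 were overlapped in WT replicate 2, and 70.8% (69.2 to 72.2) and 77.5% (76.1 to 78.8) in the longer lists of ΔcIDR replicates 1 and 2.

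P300 peak lists were shorter in ΔcIDR than in WT cells, and one WT library set most of the difference. The ΔcIDR libraries held 1338 and 1304 peaks (mean 1321 ± 24.0, SD, n = 2) and the WT libraries 1466 and 2487 (mean 1976.5 ± 722, SD, n = 2). The log2 difference was −0.53, a ratio of 0.692, with p = 0.33 by the two-sided exact permutation test (n = 2 per genotype), again the smallest this test allows. Without WT replicate 2 the log2 difference was −0.15, and without WT replicate 1 it was −0.91. At a −log10 q of at least 5 it was −0.29 (exact permutation p = 0.67, n = 2 per genotype), and the genotypes no longer separated, with 531 and 586 peaks in ΔcIDR and 582 and 804 in WT libraries. The means differed by less than the gap of 1021 peaks between the WT replicates.

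A larger share of P300 than of YY1 regions was held by a single library. The P300 peaks merged into 4528 regions, of which 3355 (74.1%) were in a single library and 288 in all 4. Of the 634 regions in both WT libraries, 70.7% (67.0 to 74.1) lay in at least 1 ΔcIDR list, and of the 471 in both ΔcIDR libraries, 86.6% (83.3 to 89.4) lay in at least 1 WT list. The 63 ΔcIDR-only and 186 WT-only regions stood beside 49 and 130, and 114 and 63, for the other divisions into pairs. At equal length (1304 peaks) there were 80 ΔcIDR-only and 107 WT-only regions, and the Jaccard index was 0.227 between ΔcIDR libraries, 0.233 between WT libraries and 0.211 to 0.224 between genotypes. Without WT replicate 1 or 2 the WT-only count was 1714 or 856. The ΔcIDR-only count was 614 or 684 without ΔcIDR replicate 1 or 2, and 110 or 136 without WT replicate 1 or 2.

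The leading WT-only P300 region was on chromosome 3 from 3002017 to 3002175, with folds of 10.0 and 8.99 in WT replicates 1 and 2. It lay within 3 kb of the leading WT-only YY1 region. The second was on chromosome 11 from 3087382 to 3087605, with folds of 9.77 and 11.4. The leading ΔcIDR-only P300 regions were on chromosome 14 from 19384083 to 19384352, with folds of 11.7 and 9.46 in ΔcIDR replicates 1 and 2, and on the same chromosome from 18434190 to 18434357, with 9.06 and 11.4. Of the 10 best-ranked ΔcIDR-only P300 regions, 7 lay in windows crowded with P300 peaks in every library, while 45 of the 63 regions of the whole class were left when those windows were removed. The best-ranked shared P300 regions were on chromosome 2 from 98496597 to 98497677, chromosome 9 from 35216512 to 35216887, chromosome 6 from 103626012 to 103626254 and chromosome 12 from 3159872 to 3160121, which were also among the leading YY1 regions. P300 folds at the chromosome 12 region were 76.8 in both ΔcIDR libraries and 77.1 and 78.2 in the WT libraries.

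P300 peaks were concentrated in 13 windows of 1 Mb on chromosomes 4, 5, 8, 9, 11, 13 and 14. These windows held 21.4% (19.3 to 23.7) and 25.1% (22.8 to 27.5) of the P300 peaks in the ΔcIDR libraries, a mean of 23.3% ± 2.56 (SD, n = 2). In the WT libraries they held 18.3% (16.4 to 20.3) and 13.1% (11.9 to 14.5), a mean of 15.7% ± 3.63 (SD, n = 2). The peak numbers in the windows were 287 and 327 in ΔcIDR and 268 and 327 in WT cells, so the shares differed mainly through the peaks elsewhere. The most crowded window, on chromosome 8 from 20 to 21 Mb, held 50 to 55 P300 peaks and 17 to 20 YY1 peaks per library. Of the YY1 peaks, the 13 windows held 1.48% and 0.966% in ΔcIDR and 2.92% and 2.17% in WT cells. The windows were picked for their P300 peaks, so a higher share for P300 than for YY1 follows in part from that choice. YY1 peaks in the windows numbered 136 and 150 in ΔcIDR and 103 and 127 in WT libraries, which differed far less than the list lengths.

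**Figure D3:**
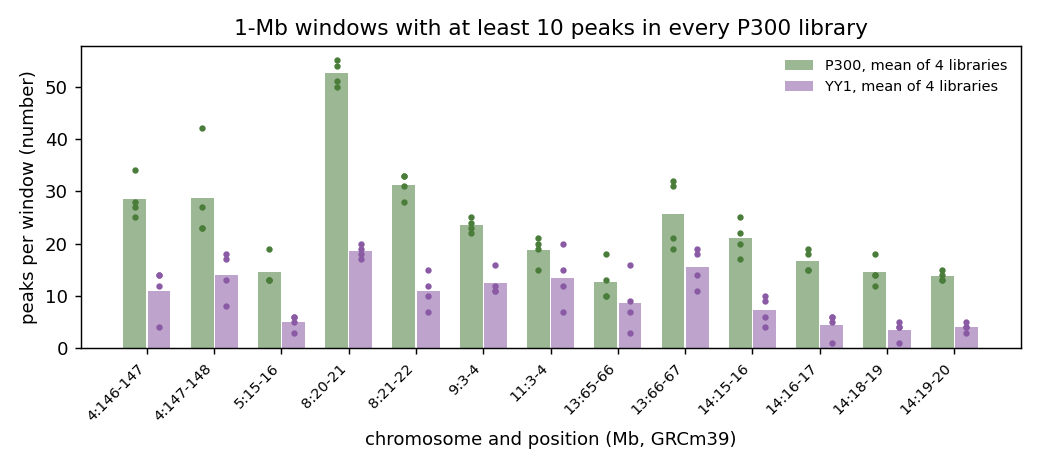
Peaks per library (vertical axis, number) in the 13 windows of 1 Mb with at least 10 peaks in every P300 library (horizontal axis, chromosome and position in Mb on GRCm39). Bars are means of the 4 libraries of P300 (green) or YY1 (purple) and points single libraries; the window on chromosome 8 from 20 to 21 Mb holds 50 to 55 P300 peaks.

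The genotype difference in peak number went in opposite directions for the antibodies. The log2 ratio was 1.93 higher for YY1 than for P300, with p = 0.056 by the exact permutation test, the smallest the 36 assignments of these libraries allow. At a −log10 q of at least 5 the difference was 1.38 (exact permutation p = 0.11).

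YY1 and P300 regions overlapped more often than shifted positions did, yet few YY1 regions overlapped a P300 region. Of the 2012 YY1 regions shared by all libraries, 77 (3.83%, 3.07 to 4.76) overlapped a P300 region shared by all P300 libraries, against a mean of 0.23 and a maximum of 3 after circular shifts (permutation p = 0.001, the smallest 1000 shifts can give). Seen from P300, 27.4% of its 288 shared regions overlapped. Among regions in both ΔcIDR libraries, 138 of 5686 YY1 regions (2.43%, 2.06 to 2.86) overlapped P300, and among regions in both WT libraries 133 of 2272 (5.85%, 4.96 to 6.90). These sets differ in length, and the genotype difference in the share was not tested. The overlaps include the positions called in all 8 libraries, which held most of the best-ranked peaks of every library. No control library was analysed here, so the shifts cannot tell binding of both proteins from signal that recurs at fixed positions.

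The ΔcIDR-only YY1 regions coincided with P300 less often than the shared YY1 regions did. Of the 1914 regions, 12 (0.627%, 0.359 to 1.09) overlapped a P300 region of both ΔcIDR libraries, against 91 of the 2012 shared YY1 regions (4.52%, 3.70 to 5.52). The 12 overlaps still exceeded those of shifted positions, with a mean of 0.259 and a maximum of 4 (permutation p = 0.001, the smallest 1000 shifts can give). The odds ratio was 0.133 (two-sided Fisher's exact test, p = 1.11e-15). Against P300 regions of both WT libraries the shares were 0.679% and 4.92%, with an odds ratio of 0.132 (two-sided Fisher's exact test, p = 4.27e-17). Regions are not independent replicates, so these tests describe the region sets of these libraries. The shared regions also ranked higher in their lists, as given above. Of the 91 shared regions, 77 overlapped a P300 region of all P300 libraries and so were called in all 8 libraries. A region called in every library belongs to the shared class by definition, while a ΔcIDR-only region could still overlap P300. Signal that recurs at fixed positions in every library, whatever the antibody, would thus raise the share of the shared class only. The contrast cannot be told apart from such signal here, and it does not show that ΔcIDR-only regions avoid P300.

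Regions of 1 genotype that were found with both antibodies were few. The 4 WT libraries shared 2 regions found in no ΔcIDR library, on chromosome 11 from 31872599 to 31872852 and on chromosome 8 from 41834481 to 41835024. The 4 ΔcIDR libraries shared 4 regions found in no WT library, on chromosome 1 from 183078224 to 183078833, chromosome 5 from 139311442 to 139311960, chromosome 11 from 96868296 to 96868906 and chromosome 12 from 72132345 to 72132872. These were chosen after their values were seen. Other choices of 2 YY1 and 2 P300 libraries gave up to 9 such regions, and 12 of the 36 choices gave at least 2.

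The share of YY1 peaks on chromosome 8 was lower in ΔcIDR than in WT cells. It was 5.24% (4.80 to 5.72) and 5.46% (5.11 to 5.83) in the ΔcIDR libraries, a mean of 5.35% ± 0.155 (SD, n = 2), against 7.06% (6.26 to 7.95) and 6.42% (5.82 to 7.08) in the WT libraries, a mean of 6.74% ± 0.453 (SD, n = 2). Chromosome 6 carried 5.42% and 5.25% of the ΔcIDR peaks and 6.35% and 6.28% of the WT peaks. Both ΔcIDR shares lay on the same side of both WT shares on 15 of 21 chromosomes for YY1 (6 lower, 9 higher) and on 12 of 21 for P300 (8 lower, 4 higher), where chance gives 33.3% for a single chromosome. The shares within a library depend on each other and come from the same 4 libraries per antibody, so these counts are not a test. For P300, chromosome 8 held 11.0% and 11.3% of the peaks in ΔcIDR and 11.1% and 9.41% in WT libraries, with overlapping intervals.

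**Figure D4:**
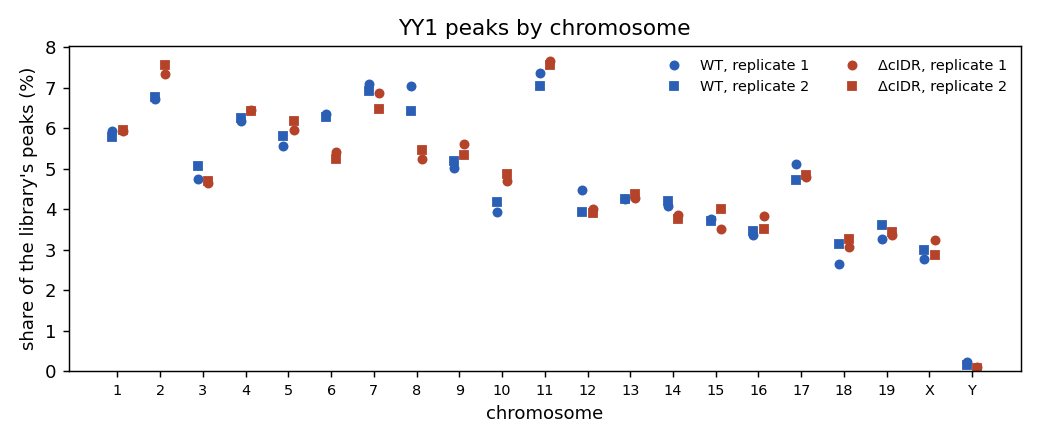
Share of each YY1 library's peaks (vertical axis, percent) on each chromosome (horizontal axis). Blue points are WT and red points ΔcIDR libraries, circles replicate 1 and squares replicate 2; on chromosome 8 the ΔcIDR libraries sit at 5.24% and 5.46% and the WT libraries at 7.06% and 6.42%.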

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

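The tests of explanations in this part were chosen after the results were seen. The difference between the antibodies in the genotype effect on peak number, a log2 value of 1.93, drew attention because both ΔcIDR lists were longer than both WT lists for YY1 and shorter for P300. The exact permutation test of that difference gave p = 0.056, its smallest possible value.

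Longer YY1 lists in ΔcIDR cells were weighed against technical explanations. Recovered background reads per 100 bp of shortest peak were lower in ΔcIDR libraries, at a ratio of 0.618 to WT. They argue against deeper sequencing, if the background came from the library itself. A surplus of weak peaks as the whole cause is argued against by the log2 ratio at a −log10 q of at least 5. That log2 ratio of peak numbers was still 1.09. A library-wide difference in signal over background may account for much of the pattern. This was read at the 1721 regions called in all YY1 libraries and free of P300 peaks. Summit reads over background there were higher in ΔcIDR by a median log2 of 1.00 (SD 0.35 across regions). The medians per library (30.7 and 49.4 in ΔcIDR, 17.96 and 20.84 in WT) followed the order of the list lengths. The backgrounds they were divided by (0.586 and 0.324 in ΔcIDR, 0.835 and 0.816 in WT) ran in the reverse order. The order of the medians may therefore come from that division and is no separate support. The division by each library's background adds 0.92 to every region and the summit reads themselves differed by a median log2 of 0.08, and the weakest pair of libraries from different genotypes differed by 0.55 where the ΔcIDR replicates differed by −0.72, so the shift is not larger than the spread within a genotype in every pair. More YY1 on chromatin and a more efficient assay both raise all regions together, and the genotype stays open, as untested.

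The windows crowded with P300 peaks were weighed as a second pattern. Whether their signal depends on the antibody stays open. The YY1 genotype shift at 1710 regions without P300 outside the windows served for comparison. At 17 regions of the windows with peaks in all P300 libraries the shift was lower by 0.32 (permutation p = 0.0005). Chromosome 8, whose offset is described further on, was then left out of the window regions but kept among the 1710. That left 10 window regions with a difference of 0.057 (permutation p = 0.60), too few to decide. The step also removed the most crowded window, on chromosome 8, so it cannot tell that chromosome's offset from a trait of its windows. Outside the windows the difference was 0.61 at 45 regions (permutation p = 0.0001, the smallest 10000 permutations can give), and all these tests treat regions of the same libraries as independent, which they are not. That the windows set the shorter P300 lists of ΔcIDR cells is argued against by the log2 ratio outside them, −0.67, against −0.53 with them. Control libraries were not analysed here, and no biological explanation was tested for this pattern.

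Peaks on the sequence named dm, which the labels do not describe, were above a set floor of 3 in 7 libraries. There were 82 in YY1 ΔcIDR replicate 2, 4 and 9 in YY1 WT replicates 1 and 2, 9 and 37 in P300 ΔcIDR replicates 1 and 2, and 27 and 21 in P300 WT replicates 1 and 2. YY1 ΔcIDR replicate 1 had 3. Peaks on this sequence reached position 143715072, in YY1 ΔcIDR replicate 2. Whether it stands for DNA added as a reference, and whether libraries were scaled by it, is not given in the sources used here. Whole reads at 100% of the peaks tried in every library argue against summit reads multiplied by a scale factor. Other ways of scaling stay open, so the comparisons of peak numbers between libraries carry that limit.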

How the results depend on the processing

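The coverage of regions by at least 50% and the removal of the crowded windows were chosen after the data were examined, and the other settings before. Differences in peak number kept their sign under every setting run, but at a −log10 q of at least 5 the P300 value shrank to −0.29 (exact permutation p = 0.67) with overlapping genotypes, the difference between the antibodies to 1.38 (p = 0.11 by exact permutation) and the YY1 value to 1.09. The cause was not tested. Leaving out 1 library gave log2 differences of 1.02 to 1.77 for YY1, −0.91 to −0.15 for P300 and 1.55 to 2.31 between the antibodies. No exact permutation test of 2 against 2 libraries, or of both antibodies together, can pass 0.05, so these tests say nothing about stability. Replicate numbers may mark nothing beyond a name. With the replicate block the values were the same by construction, at 1.40 for YY1, −0.53 for P300 and 1.93 between them. Within-number differences were 1.38 and 1.41 for YY1 and −0.13 and −0.93 for P300. The sign-flip test of 2 pairs cannot go under 0.5.

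Region counts moved more. At a −log10 q of at least 5, YY1 gave 742 ΔcIDR-only and 29 WT-only regions, and P300 32 and 53. At a fold of at least 5 they were 1118 and 36 for YY1, and 38 and 94 for P300. These settings keep fewer peaks, which lowers the counts by construction. Lists of equal length, which remove the difference in peak number by construction, gave 310 and 196 for YY1 and 107 WT-only regions for P300. Leaving out 1 library, which asks less of the arm left with 1, gave 2287 to 10644 ΔcIDR-only and 114 to 1256 WT-only regions for YY1, and 110 to 684 and 261 to 1714 for P300. Summit windows, coverage by at least 50% and the removal of the crowded windows left each count within 1.5 times its main value. The planned condition for summit windows asked that a window cover at least 50% of its region or lie in it by at least 50%, and every window lies wholly in its merged region, so the condition removed nothing. In every setting other than single-library ones, YY1 had more ΔcIDR-only and P300 more WT-only regions.

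Alternatives for shares at promoters, gene lists, the YY1 motif and shared promoters were not run, since no genome or annotation of the build was used. Read totals are not given in the files. Recovered backgrounds were 0.324 to 1.01 reads and median summits 8 to 13 reads, and the longest YY1 list had the lowest background. How far depth limits the lists was not tested.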

Other observations

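The tests in this part were all chosen after the result was seen. At regions called in all 4 YY1 libraries and free of P300 peaks, the genotype shift of summit reads over background was lower on chromosome 8 than on the genome, by an offset of −0.28 ± 0.03 (log2, SE over 107 regions, permutation p = 0.0001, the smallest 10000 permutations can give, and 0.001 after Benjamini-Hochberg adjustment over 20 chromosomes). Smaller offsets passed the same adjustment at 0.05 on chromosomes 6 (−0.14), 13 (−0.12), 7 (0.08), 11 (0.10) and 17 (0.09). On chromosome 6 the pairs of different genotype ranged from −0.16 to −0.12 with −0.019 and −0.020 within genotypes, and on chromosome 13 from −0.13 to −0.10 with 0.0026 and 0.021. On chromosome 11 these pairs ranged from 0.078 to 0.119 with −0.035 and 0.0056 within genotypes. On chromosome 17 they ranged from 0.064 to 0.124 with −0.032 and 0.029, and on chromosome 7 from 0.051 to 0.10 with 0.044 and 0.0053. Regions on a chromosome are not independent samples, and the permutation treats them as such.

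A candidate explanation for chromosome 8 is fewer copies of it, relative to the rest of the genome, in the ΔcIDR than in the WT cells. A single cluster of regions is argued against by the chromosome's 3 parts, whose offsets were −0.31, −0.28 and −0.24. The offset of −0.28 appeared in all 4 pairs of libraries of different genotype, from −0.28 to −0.27. It was −0.00816 and −0.00457 within genotypes, as a difference between the cells would give. The pairs share the same 4 libraries, so with values near 0 within genotypes they must agree and are not separate checks. Chromosomes 6 and 13 showed the same kind of pattern at a smaller size, and chromosomes 11 and 17 with the opposite sign, so it is not particular to chromosome 8. P300 libraries showed −0.30 ± 0.08 at 16 regions outside the crowded windows (permutation p = 0.0002), but −0.09 ± 0.05 over all 54 regions of the chromosome. A full step from 3 copies to 2 would give −0.58, so the YY1 value may point to a part of the cells only, and whether it goes with the Alkbh5 deletion or with the line each genotype was grown from was not tested.

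At regions called in all P300 libraries, summit reads over background were lower in ΔcIDR cells by a median log2 of −0.23 (262 regions, SD 0.32). Reads before division by the background were higher in ΔcIDR cells by 0.05. The lower value thus came from the division, which added −0.28 to every region.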
